A study of Drosophila melanogaster with 9 samples.

How the data were processed

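RNA was measured by sequencing in 9 libraries of Drosophila Kc167 cells, with 3 libraries in each of 3 groups. Per the labels' protocols, 15 µg of dsRNA was given to each culture, cells were collected on day 7, total RNA was extracted with Trizol, and libraries were sequenced on an Illumina HiSeq instrument. Library selection, strandedness, read numbers and the target of the control dsRNA are not given in the sources used here, so the total depth is unknown. Counting error was not modelled, and only the spread between libraries shows the precision. The labels do not say whether replicates are separate cultures, so each p measures the spread between these libraries and no more.

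The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) for each of 14797 genes and each library, with their mean FPKM per group and the q-value of 2 of their own comparisons. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 and Bowtie2 2.2.6 to the dm6 build, FPKM values came from Cufflinks and Cuffdiff, and R 3.2.3 was used. How the authors scaled FPKM between libraries is not given in the sources used here. Each deposited group mean matched the mean of its 3 libraries to a relative difference of at most 7.52e-06. The authors' remaining columns of fold changes and p-values hold cells that are not numbers and were not used here. The notes name dm6, but 247 deposited positions carry chromosome names found only in release 5 of the genome. Of 13462 genes found by FlyBase identifier in the dm6 reference annotation, 786 had a start within 1 base of the deposited one. The coordinates given here therefore come from that dm6 annotation, matched by FlyBase identifier, and not from the authors' positions. Gene symbols are those of the deposited file, 5 symbols were damaged or empty, and newer names follow in brackets. All 37 mitochondrial genes were listed at 0 in every library. Without a statement on strand, reads of overlapping genes cannot be told apart, and those of near-identical copies such as ph-p and ph-d may be split between them.

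Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with linear models and moderated statistics with a mean-variance trend. Genes needed at least 0.5 FPKM in at least 3 of the 9 libraries, which left 8853. One fit of all 3 groups gave 3 comparisons with a shared estimate of spread, and p values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. Every adjusted p comes from limma unless another source is named. The pseudocount makes log2 changes of genes near 0 FPKM smaller than their ratios. Groups are given as mean ± SD of 3 libraries in FPKM and log2 changes as estimate ± SE.

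The comparisons, the tests, the rule for naming genes and 25 gene lists were fixed before the data were examined. Lists with at least 4 tested members, 23 in number, were tested with camera at its preset correlation of 0.01, and then with an estimated correlation and with fry. They cover the HOX genes, Polycomb target transcription factors, the Polycomb and trithorax groups, CtBP partner factors, and the Notch, JAK-STAT, Wnt, and Hedgehog and Dpp pathways. They also cover immune, ecdysone response, cell cycle, apoptosis, heat shock and stress, RNA interference, glycolysis, ribosomal protein and reference genes, and markers of plasmatocytes, of crystal cells and lamellocytes, of neurons, of muscle and of germline. The non-homeotic genes of the HOX clusters had 1 tested member, bcd, which was called in no comparison, and the fat body and gut markers had 0. The rule named the knockdown targets, the 8 homeotic genes, the 10 largest changes each way among called genes whose groups did not overlap, up to 4 members per list with the smallest adjusted p, all members of lists of 8 or fewer genes, and the 10 largest opposite changes each way. Genes known only by a CG or CR number were left out of the ranked parts.

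The first 2 comparisons share the ph+E(z) libraries, so their changes were also compared with 100 simulated sets of libraries without effects and with ph+E(z) libraries held out in turn. Alternatives covered the pseudocount, the filter, the scaling, the trend, robust moderation, array weights, fits of 2 groups, a block for the replicate number, a correction for transcript length and leaving out each library. The length correction was added after the data were seen and covers the 92.09% of tested genes that have a transcript length. The fit was tested on simulated data with 200 of 8853 genes changed. There each gene had the same spread in all 9 libraries and was drawn independently of other genes. The real libraries differ in spread, so the rates below need not hold for them. For ph+E(z) against control it recovered 51% of 2-fold and 85% of 4-fold changes, with 6.85% of calls false. For the addition of CtBP RNAi these were 49%, 91% and 7.28%, and for all 3 targets against control 56%, 87% and 2.05%. All 3 simulations used the same levels and spread, so these rates differ only by the random draw and do not rank the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.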

Results

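Gene expression was measured by RNA sequencing in Kc167 cells, an embryonic Drosophila cell line that resembles hemocytes, the blood cells of the fly. The 9 libraries, 3 per group, came from cells treated for 7 days with control dsRNA, with dsRNA against ph and E(z), or with dsRNA against ph, E(z) and CtBP. Polyhomeotic, encoded by the tandem copies ph-p and ph-d, is a subunit of Polycomb repressive complex 1. E(z) is the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2, and CtBP is a transcriptional corepressor. FPKM summed to between 725406 and 908290 per library, and 8219 to 8632 genes reached 0.5 FPKM. The library labelled control replicate 1 stood apart from the others. Ribosomal protein genes took 39.6% of its FPKM, against 26.4% to 30.8% in the other 8 libraries. Its log2 values deviated from the other 2 control libraries with an SD of 1.03, against 0.524 to 0.695 for each other library and its own group.

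The knockdown targets were examined first in every library. E(z), FBgn0000629 on chromosome 3L at 10634575 to 10638130 (dm6), lay at 43.4, 37.4 and 31.2 FPKM in the control libraries. In the 6 libraries treated against it, E(z) lay between 8.29 and 12.1 FPKM, and it fell by 1.90 ± 0.18 on the log2 scale with ph+E(z) RNAi (adjusted p = 0.0011). CtBP, FBgn0020496 on 3R at 13011649 to 13026275, was at 215 ± 8.96 FPKM with ph+E(z) RNAi and 52.2 ± 12.3 once CtBP was also targeted. That was a fall of 2.06 ± 0.16 (adjusted p = 0.00121), and the 3 libraries held 49.0, 41.8 and 65.8 FPKM. The ph-p gene, FBgn0004861 on X at 2126210 to 2138371, measured 18.9 and 18.1 FPKM in control replicates 2 and 3. With ph+E(z) RNAi it measured 7.15, 8.02 and 7.28 FPKM, and with all 3 targets 7.22, 7.25 and 10.3. In the library labelled control replicate 1 it measured 4.64 FPKM, below all 6 knockdown libraries and against its label, while E(z) in that library went with its label. With all libraries, ph-p differed by -0.62 ± 0.46 between ph+E(z) and control RNAi (adjusted p = 0.486). Without the library labelled control replicate 1 it fell by 1.25 ± 0.17 (adjusted p = 0.00617). The neighbouring copy ph-d, FBgn0004860 on X at 2115727 to 2123286, measured 1.26, 5.72 and 4.87 FPKM in the control libraries and 4.21, 4.62 and 4.91 with ph+E(z) RNAi (adjusted p = 0.629). Values of this near-identical pair are uncertain.

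**Figure D1:**
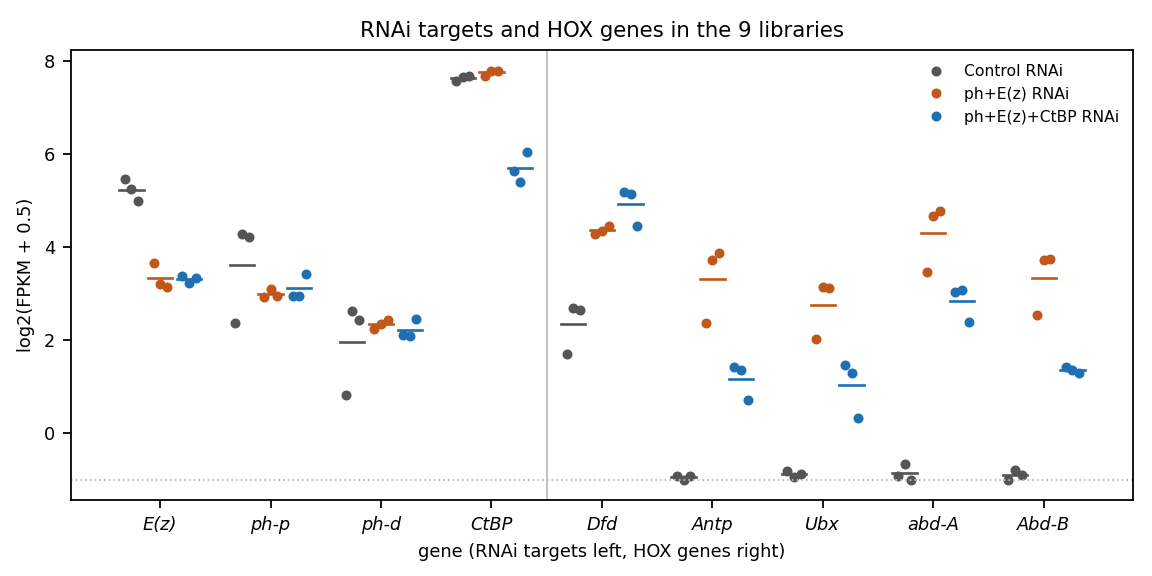
Expression of the 4 knockdown targets and of the 5 tested HOX genes, as log2(FPKM + 0.5), in the 9 libraries by RNAi group. Points are libraries, lines are group means, and the dotted line is the value of 0 FPKM. E(z) is at 31.2 FPKM or more in the control libraries and at 12.1 or less in the other 6, and ph-p is at 4.64 FPKM in the library labelled control replicate 1.

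The first comparison, ph+E(z) RNAi against control RNAi, asks which genes respond when both Polycomb complexes are targeted, with the HOX genes as the readout that the series title names. All 5 HOX genes that could be tested rose, and all 3 treated libraries lay above all 3 control libraries for each. Antp, Ubx, abd-A and Abd-B, at 0.135 FPKM or less in control libraries, passed the filter only through treated libraries and could not fall. These genes encode transcription factors that set segment identity. abd-A, FBgn0000014 on 3R at 16807214 to 16830049, went from 0.0542 ± 0.0713 to 20.8 ± 8.98 FPKM, a log2 change of 5.16 ± 0.36 (adjusted p = 0.000241). Antp, FBgn0260642 at 6896253 to 6999228 on the same arm, went from 0.0219 ± 0.019 to 10.5 ± 5.13 FPKM, a change of 4.26 ± 0.39 (adjusted p = 0.00105). Abd-B, FBgn0000015 at 16927212 to 16972236, went from 0.0394 ± 0.0414 to 10.3 ± 4.28 FPKM, a change of 4.23 ± 0.31 (adjusted p = 0.000299). Ubx, FBgn0003944 at 16656623 to 16734426, went from 0.0474 ± 0.0221 to 6.73 ± 2.75 FPKM, a change of 3.64 ± 0.39 (adjusted p = 0.00216). Dfd, FBgn0000439 at 6791836 to 6802428, was already present in control cells at 4.82 ± 1.78 FPKM and reached 20.1 ± 1.26, a change of 2.02 ± 0.29 (adjusted p = 0.00811). The other HOX genes were too low to test with ph+E(z) RNAi, lab at 0.522 ± 0.307, pb at 0.218 ± 0.161 and Scr at 0.0473 ± 0.082 FPKM. All 5 calls held when any of the 9 libraries was left out. As a list, the HOX genes were higher than other genes by camera (adjusted p = 3.63e-10), with an adjusted p = 0.101 with an estimated correlation.

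Across the genome, 347 of 8853 genes passed the test, 228 higher and 119 lower, and in all 347 the 3 libraries of one group lay wholly above those of the other. Groups did not overlap for 26.7% of all tested genes, where chance gives 10%. Several developmental transcription factors rose. The head gene oc, which encodes Orthodenticle, went from 0.0969 ± 0.0534 to 30.5 ± 9.84 FPKM, a log2 change of 5.64 ± 0.30 (adjusted p = 0.000154). The posterior determinant cad rose by 5.32 ± 0.31, the tracheal gene rib by 4.72 ± 0.32, the GATA factor gene pnr by 4.43 ± 0.39, drm by 4.15 ± 0.27 and the retinal determination gene dac by 3.52 ± 0.23. Adjusted p for these 5 genes lay between 0.000154 and 0.000962. Of 69 Polycomb target transcription factors outside the HOX clusters, 28 reached the FPKM filter. Of these 28, 19 rose, 0 fell and 9 did not pass the test. Members near 0 in control cells, such as dac, reached the filter only through treated libraries and could not fall. The absence of falls is therefore no separate evidence. Adjusted over the list alone 27 were higher, and camera gave an adjusted p = 7.09e-29, which was an adjusted p = 0.101 with an estimated correlation. The cell death activator rpr went from 1.98 ± 1.05 to 45.0 ± 3.76 FPKM, a change of 4.30 ± 0.37 (adjusted p = 0.000789). Among genes that fell, the acyltransferase gene fu12 (Agpat2) went from 21.8 ± 2.15 to 4.65 ± 1.11 FPKM, a change of -2.13 ± 0.21 (adjusted p = 0.00136). The cytochrome P450 gene Cyp28d1 fell by 1.70 ± 0.25 (adjusted p = 0.00842). At least 2-fold changes made up 263 of the calls, 181 higher and 82 lower. The count of called genes was 602 without the library labelled control replicate 1, 186 without control replicate 2, 164 without control replicate 3, 108 and 126 without ph+E(z) replicates 2 and 3, and 228 without replicate 1 of the group with all 3 targets. Of changes of at least 2-fold, 168 and 146 were called without control replicates 2 and 3, and 102 and 116 without ph+E(z) replicates 2 and 3.

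Hemocyte genes also moved with ph+E(z) RNAi. Of 24 tested plasmatocyte markers, genes of macrophage-like blood cells, 6 rose, 1 fell and 17 did not pass, with a median log2 change of 0.97. Adjusted over the list alone 12 were higher and 2 lower, and camera called the list higher (adjusted p = 2.2e-07), with an adjusted p = 0.172 with an estimated correlation. The phagocytosis receptor family gene nimB4 went from 6.05 ± 0.877 to 56.2 ± 19.5 FPKM, a change of 3.05 ± 0.27 (adjusted p = 0.000897). The abundant transcript Nplp2 went from 1307 ± 389.5 to 15379.9 ± 5399.7 FPKM, a change of 3.52 ± 0.35 (adjusted p = 0.00145). The receptor gene nimC1 rose by 1.45 ± 0.23 (adjusted p = 0.0138), a call lost without control replicate 3 (0.0549) and without ph+E(z) replicates 2 (0.0822) and 3 (0.0747). The member that fell was Cg25C (Col4a1), a type IV collagen gene named only after its values were seen, with a change of -1.29. Its call was lost without control replicate 2 or 3, ph+E(z) replicate 2 or 3, or any library with all 3 targets except replicate 3, and 2 members fell without ph+E(z) replicate 1 or that last library. The count of 6 became 3 without control replicate 2 or 3 and 2 without ph+E(z) replicate 2 or 3. Of 10 tested markers of crystal cells and lamellocytes, the other hemocyte types, 2 rose and 8 did not pass. Camera called that list higher (adjusted p = 0.000364), with an adjusted p = 0.101 with an estimated correlation, and 5 were higher adjusted over the list alone. Its zinc finger gene peb (hindsight) went from 0.27 ± 0.062 to 4.15 ± 1.46 FPKM, a change of 2.55 ± 0.28 (adjusted p = 0.00267). The count of 2 was 4 without the library labelled control replicate 1, and 1 without control replicate 2 or 3 or ph+E(z) replicate 2 or 3.

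Among the Polycomb group itself, 2 of 24 genes rose, 1 fell, E(z), and 21 did not pass (camera adjusted p = 0.383). Those that rose were the related neighbours Psc and Su(z)2, which encode ring finger proteins of Polycomb complex 1. Psc went from 8.03 ± 5.51 to 59.9 ± 14.2 FPKM, a log2 change of 3.15 ± 0.59 (adjusted p = 0.0247). That call was lost without ph+E(z) replicate 2 (0.11) or 3 (0.111) and without replicate 1 of the group with all 3 targets (0.0505). Su(z)2 went from 15 ± 9.51 to 88.7 ± 21.7 FPKM, a change of 2.79 ± 0.55 (adjusted p = 0.0292). It was lost without ph+E(z) replicate 1 (0.0528), 2 (0.127) or 3 (0.125) and without replicate 1 (0.0559) or 2 (0.0557) of the group with all 3 targets. In the library labelled control replicate 1, Psc lay at 1.67 FPKM, against 11.3 and 11.2 in control replicates 2 and 3. Su(z)2 lay there at 4.02 FPKM, against 20.5 and 20.4, so that library enlarges both changes. The immune list had 4 of 22 genes higher (camera adjusted p = 0.176), and 2 without control replicate 3 or ph+E(z) replicate 1, 0 without ph+E(z) replicate 2 and 1 without ph+E(z) replicate 3. One was the recognition protein gene PGRP-LF, which rose by 1.45 ± 0.21 (adjusted p = 0.00749, and 0.0514 without ph+E(z) replicate 2). The apoptosis list had 3 of 14 higher (camera adjusted p = 0.27), and 1 without control replicate 2 or ph+E(z) replicate 2 or 3. The reference gene list had 1 of 9 higher, the actin gene Act42A (camera adjusted p = 0.888). Act42A rose by 1.25 ± 0.19 (adjusted p = 0.00979), and this became 0.0598 and 0.0516 without ph+E(z) replicates 2 and 3. Glycolysis genes were lower as a list (15 tested, median -0.85, camera adjusted p = 5.61e-06, and adjusted p = 0.432 with an estimated correlation). In it 1 gene fell over all genes tested, and adjusted over the list alone 12 were lower and 2 higher. Without the library labelled control replicate 1, 8 of the 15 were called lower, 0 without any other control library or any ph+E(z) library, and 2 without replicate 3 of the group with all 3 targets. Heat shock and stress genes had 0 of 30 called and a median of -0.32 (camera adjusted p = 0.00257, and adjusted p = 0.432 with an estimated correlation). In this list 3 were lower and 1 higher without the library labelled control replicate 1, 1 was lower without ph+E(z) replicate 1, and 2 without replicate 3 of the group with all 3 targets. Ribosomal protein genes had 0 of 82 called and a median of -0.20 (camera adjusted p = 0.00183, and adjusted p = 0.854 with an estimated correlation). Without the library labelled control replicate 1, in which these genes took 39.6% of FPKM, their direction turned to higher (adjusted p = 0.331). It also turned with array weights (0.81), and with quantile normalization the list was no longer called (0.133).

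The remaining lists were not called with ph+E(z) RNAi, and over all 16 lists without a call the camera adjusted p ran from 0.0766 to 0.935. Higher members numbered 1 of 15 in the Notch pathway and 1 of 17 in the Hedgehog and Dpp pathways. The former call was lost without any library except replicate 3 of the group with all 3 targets, and the latter without control replicate 2 or 3 or any ph+E(z) library. The Hedgehog and Dpp list had 2 higher without the library labelled control replicate 1. There were 0 calls among 24 trithorax group genes, 17 CtBP partner factors, 12 JAK-STAT, 13 Wnt, 16 ecdysone response and 38 cell cycle genes. None of 11 neuron, 8 muscle and 16 germline markers or 12 RNA interference genes was called by limma either, where 1529 of all 8853 genes had an unadjusted p under 0.05. No list held its call with an estimated correlation in any of the 3 comparisons. CtBP partner factors were called higher without a filter (0.0397), with quantile normalization (0.0379), without control replicate 2 (0.0125) or 3 (0.0126) and without ph+E(z) replicate 1 (0.0308), with up to 0.765 under other alternatives. Neuron markers were called higher with the stricter filter (0.0315) and without control replicate 2 (0.0229) or 3 (0.0193), with up to 0.938 elsewhere. The immune list was called higher with the stricter filter (0.0223) and reached 0.33 under other alternatives. For no called list did the median, the mean and the direction of the test differ in sign.

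**Figure D2:**
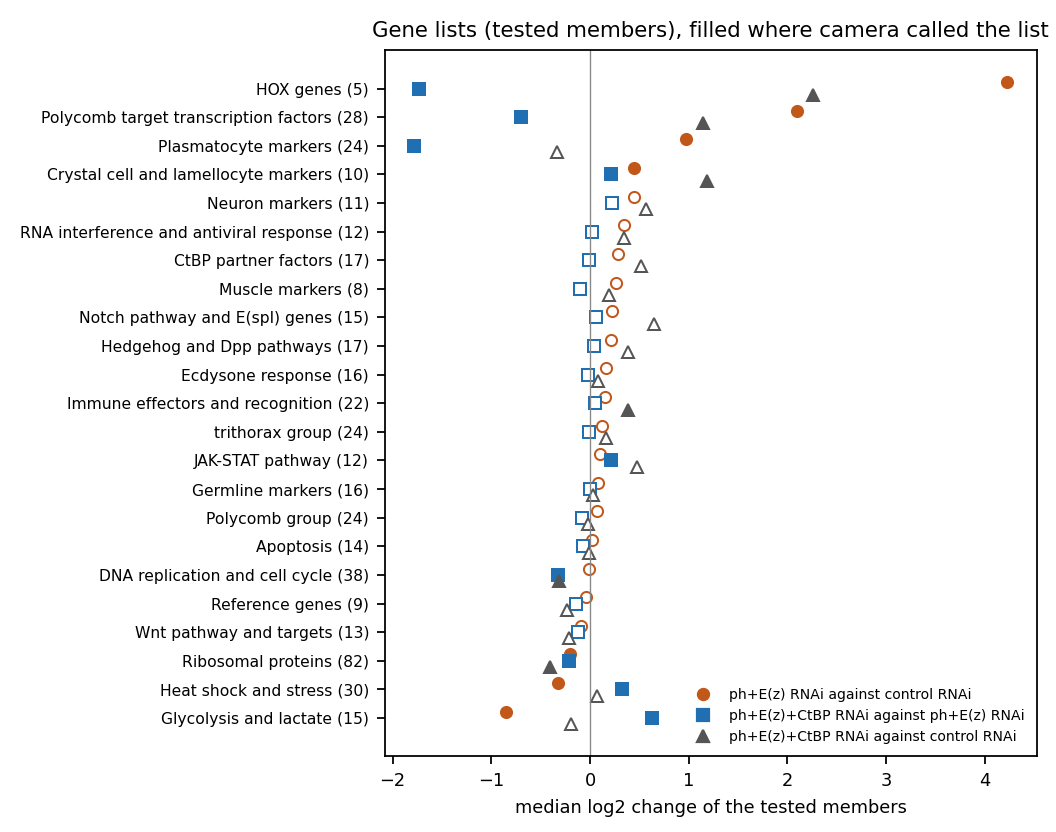
Median log2 change of the tested members of each gene list in the 3 comparisons, with filled symbols where camera with its preset correlation called the list. The HOX list lies at 4.23 for ph+E(z) against control and at -1.73 on adding CtBP RNAi. The plasmatocyte list lies at 0.97 and -1.78, and the ribosomal protein list, at -0.20 for ph+E(z) against control, turns to higher without the library labelled control replicate 1.

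The second comparison, ph+E(z)+CtBP RNAi against ph+E(z) RNAi, asks what changes when CtBP is also targeted in cells in which the Polycomb genes are already targeted, the setting in which the series title places CtBP in HOX gene activation. Of the 5 tested HOX genes 3 fell, 0 rose and 2 did not pass, and adjusted over the list alone 4 were lower. Antp went from 10.5 ± 5.13 to 1.81 ± 0.571 FPKM, a log2 change of -2.14 ± 0.39 (adjusted p = 0.0237). Abd-B went from 10.3 ± 4.28 to 2.08 ± 0.124 FPKM, a change of -1.97 ± 0.31 (adjusted p = 0.0128). Ubx went from 6.73 ± 2.75 to 1.66 ± 0.797 FPKM, a change of -1.73 ± 0.39 (adjusted p = 0.049). For each of these the 3 libraries with CtBP RNAi lay below the 3 without it. The shared estimate of spread also includes the control libraries, where these genes lay at 0.0825 FPKM or less. The pseudocount keeps the spread of such low values small, so these SE and adjusted p may be too small. abd-A, at 20.8 ± 8.98 and 6.80 ± 1.79 FPKM, differed by -1.47 ± 0.36 and did not pass (adjusted p = 0.0683). Dfd, at 20.1 ± 1.26 and 30.6 ± 7.89 FPKM, differed by 0.56 ± 0.29 in the other direction (adjusted p = 0.45). The HOX list was lower by camera (adjusted p = 0.000893), with an adjusted p = 0.395 with an estimated correlation.

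Each of these HOX calls was lost when any of several libraries was left out. Fewer libraries also lower the power of the test, so a lost call need not mean that 1 library carries the fall. The size of the falls did differ by library. In ph+E(z) replicates 1, 2 and 3, Antp lay at 4.64, 12.6 and 14.2 FPKM and Ubx at 3.55, 8.37 and 8.25. Abd-B lay there at 5.33, 12.6 and 12.9 FPKM. With all 3 targets, Antp lay at 2.19, 2.08 and 1.15 FPKM and Ubx at 2.26, 1.97 and 0.758. Each fall was therefore smaller against ph+E(z) replicate 1 than against replicates 2 and 3. Leaving out a control library keeps these log2 changes as they are and alters only the estimate of spread. No HOX gene was called without ph+E(z) replicate 2 or 3 or without replicate 1 or 2 of the group with all 3 targets, 1 was called without replicate 3 of that group, and 4 without the library labelled control replicate 1. Antp was at an adjusted p of 0.112 and 0.106 without ph+E(z) replicates 2 and 3, and at 0.0756, 0.0796 and 0.0645 without replicates 1, 2 and 3 of the group with all 3 targets. Abd-B was at 0.0691 and 0.0626 without ph+E(z) replicates 2 and 3, and at 0.0588 and 0.0622 without replicates 1 and 2 of the latter group. Ubx was at 0.0811 and 0.0814 without control replicates 2 and 3, at 0.206 and 0.204 without ph+E(z) replicates 2 and 3, and at 0.0944, 0.122 and 0.0991 without replicates 1, 2 and 3 of the group with all 3 targets. abd-A passed at 0.0367 without the library labelled control replicate 1 and at 0.0121 without ph+E(z) replicate 1.

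Adding CtBP RNAi lowered markers of plasmatocytes most clearly. Of 24 tested, 13 fell, 0 rose and 11 did not pass, with a median log2 change of -1.78. Adjusted over the list alone 14 were lower and 1 higher, and camera gave an adjusted p = 1.02e-13, which was an adjusted p = 0.163 with an estimated correlation. The extracellular matrix peroxidase gene Pxn went from 55.0 ± 4.80 to 5.51 ± 4.26 FPKM, a change of -3.42 ± 0.39 (adjusted p = 0.00428). nimB4 went from 56.2 ± 19.5 to 4.61 ± 0.509 FPKM, a change of -3.41 ± 0.27 (adjusted p = 0.00131). The collagen-binding matrix gene BM-40-SPARC went from 575 ± 31.2 to 72.4 ± 31.2 FPKM, a change of -3.06 ± 0.26 (adjusted p = 0.00137). nimC1 went from 12.2 ± 3.75 to 1.19 ± 0.126 FPKM, a change of -2.86 ± 0.23 (adjusted p = 0.00137). The hemocyte surface gene He fell by 1.66 ± 0.17 (adjusted p = 0.00284), although its annotated end overlaps a neighbouring gene, so its value is uncertain. The blood cell transcription factor gene srp, named after its values were seen, differed by -0.07 (adjusted p = 0.974). The count of 13 was 7 without ph+E(z) replicate 2, 8 without ph+E(z) replicate 3, and 7 and 8 without replicates 1 and 2 of the group with all 3 targets.

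In all, 329 genes changed on adding CtBP RNAi, 172 higher and 157 lower, and 229 changed at least 2-fold, 115 higher and 114 lower. All 329 had groups that did not overlap, as had 31.2% of all tested genes, where chance gives 10%. The glutathione transferase gene GstD2 rose most among named genes, from 3.26 ± 1.59 to 46.6 ± 8.01 FPKM, a log2 change of 3.74 ± 0.36 (adjusted p = 0.00242), though it belongs to a family of close copies and its value is uncertain. Phk-3 rose by 2.95 ± 0.39 (adjusted p = 0.00712). Epac, an exchange factor for Rap proteins regulated by cyclic AMP, went from 3.41 ± 2.11 to 23.0 ± 2.36 FPKM, a change of 2.71 ± 0.32 (adjusted p = 0.00482). The axon guidance receptor gene lea (robo2) rose by 2.01 ± 0.22 and the Activin-like ligand gene daw by 1.90 ± 0.24 (adjusted p = 0.00426 and 0.00605). The Notch target malpha went from 1.71 ± 0.569 to 7.58 ± 0.870 FPKM, a change of 1.90 ± 0.23 (adjusted p = 0.00482). The translation inhibitor gene Thor rose by 1.06 ± 0.12 (adjusted p = 0.00426) and the formin gene Fhos by 1.05 ± 0.13 (adjusted p = 0.00515). The count of called genes was 1191 without the library labelled control replicate 1, 89 and 90 without ph+E(z) replicates 2 and 3, and 115 both without replicate 1 and without replicate 2 of the group with all 3 targets. Changes of at least 2-fold numbered 79 and 82 without ph+E(z) replicates 2 and 3, and 100 and 96 without those 2 libraries with all 3 targets.

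Other lists moved in the second comparison with few calls of single genes. The 28 Polycomb target transcription factors had 4 lower and 24 not called, 9 lower adjusted over the list alone, and a median of -0.70 (camera adjusted p = 3.3e-07, and adjusted p = 0.424 with an estimated correlation). The count of 4 was 8 without the library labelled control replicate 1 or ph+E(z) replicate 1, 1 without control replicate 2 or 3, and 0 without any of the other 5 libraries. The eye gene Optix, one of the 4, fell by 2.83 ± 0.54 (adjusted p = 0.0265). Its adjusted p was 0.125 and 0.0934 without ph+E(z) replicates 2 and 3, and 0.0918, 0.0923 and 0.0784 without replicates 1, 2 and 3 of the group with all 3 targets. Cell cycle genes had 0 of 38 called, 8 lower adjusted over the list alone and a median of -0.33 (camera adjusted p = 3.67e-10, and adjusted p = 0.28 with an estimated correlation). Without the library labelled control replicate 1, 17 of them were called lower. Heat shock and stress genes had 3 of 30 higher, GstD2, Thor and Mmp1, and 1 lower, Hsc70-3, with a median of 0.32 (camera adjusted p = 8.4e-05, and adjusted p = 0.282 with an estimated correlation). None of these 4 is a small or inducible heat shock protein. Mmp1 lost its call without ph+E(z) replicate 2 (0.116) or 3 (0.13) and without replicate 1 (0.121) or 2 (0.121) of the group with all 3 targets. Hsc70-3 kept its call only without the library labelled control replicate 1 and without replicate 3 of the group with all 3 targets, with adjusted p between 0.0568 and 0.139 in the other 7 fits. Without the library labelled control replicate 1, 10 genes of this list were called higher. Glycolysis genes had 1 of 15 higher and a median of 0.62 (camera adjusted p = 9.94e-05, and adjusted p = 0.424 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone. Without the library labelled control replicate 1, 11 were called higher, and 0 were without any other library. Ribosomal protein genes had 0 of 82 called and a median of -0.21 (camera adjusted p = 7.86e-05, and adjusted p = 0.696 with an estimated correlation), and 9 were lower without the library labelled control replicate 1.

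JAK-STAT genes had 2 of 12 higher and 1 lower (camera adjusted p = 0.0397, and adjusted p = 0.282 with an estimated correlation). The higher genes numbered 5 without the library labelled control replicate 1, 0 and 1 without ph+E(z) replicates 2 and 3, and 1 without replicate 1 of the group with all 3 targets. The feedback inhibitor gene Socs36E went from 38.4 ± 11.0 to 117 ± 7.36 FPKM, a change of 1.63 ± 0.23 (adjusted p = 0.00819, and 0.051 without ph+E(z) replicate 2). The receptor gene dome rose by 0.73 ± 0.10 (adjusted p = 0.00809), a call lost without ph+E(z) replicate 2 (0.0579) or 3 (0.0555) and without replicate 1 of the group with all 3 targets (0.0502). The receptor CG14225 (et), an antagonist of the pathway and neighbour of dome, fell by 1.40 ± 0.17 (adjusted p = 0.00494). The list call itself was lost without ph+E(z) replicate 2 (0.0907) and without replicate 1 (0.0513) or 3 (0.154) of the group with all 3 targets, and also without a filter (0.0716) and with the length correction (0.093). Markers of crystal cells and lamellocytes had 1 of 10 higher, Fhos (camera adjusted p = 0.0301, and adjusted p = 0.282 with an estimated correlation). That list call was lost without replicate 1 of the group with all 3 targets (0.0916), without a filter (0.124) and with the length correction (0.0551). The other 14 lists were not called (camera adjusted p between 0.0992 and 0.908). Of these, the Wnt list was called lower without a filter (0.0272), with array weights (0.0274), with the length correction (0.0198) and without replicate 3 of the group with all 3 targets (0.0213), with up to 0.311 under other alternatives. With array weights the Polycomb group was also called lower (0.0229), and it reached 0.451 elsewhere. Among CtBP partner factors 1 of 17 was higher, and the 1 that was lower was CtBP itself. The Polycomb and trithorax groups each had 0 of 24 called.

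Genes that rose with ph+E(z) RNAi tended to be lower once CtBP was also targeted. Of the 228 genes that rose, 168 had a change below 0 on adding CtBP RNAi, or 73.7%, with a median of -0.42, and 62 passed the test downward. The ph+E(z) libraries enter both changes with opposite sign, so genes chosen as high in them are shifted below 0 in the second change without any effect, and the share and the median include that shift. Independent lists of these sizes would share 4.04 genes, a value that leaves the shared libraries out of account. The 62 include Antp, Ubx, Abd-B, nimB4, nimC1, He and Nplp2. Nplp2 went from 15379.9 ± 5399.7 to 3238 ± 906.6 FPKM, a log2 change of -2.22 ± 0.35 (adjusted p = 0.0128). It was lost without ph+E(z) replicates 2 (0.0695) and 3 (0.0657) and without replicate 1 of the group with all 3 targets (0.056). In the opposite direction, 11 genes fell and then rose, where independent lists would share 2.31. These include the lipoprotein receptor gene LpR2, which rose by 1.46 ± 0.19 on adding CtBP RNAi (adjusted p = 0.00673). Changes in the same direction in both comparisons numbered 10 higher and 3 lower, against 4.43 and 2.11 for independent lists. Over all genes the covariance of the 2 changes was -0.107, against -0.0664 in simulated libraries (range -0.109 to -0.0408 over 100 draws), so the observed value lies within that range. Over 7945 protein-coding genes, a set chosen after the data were seen, it was -0.0721, outside the simulated range of -0.0317 to -0.0209. Each gene was drawn independently in the simulated libraries, which leaves out deviations that genes share. The simulated ranges may therefore be too narrow, and no conclusion is drawn from the value outside. The correlation of the 2 changes was -0.295, against a simulated mean of -0.368 (range -0.497 to -0.24), and real changes add variance that the simulated libraries lack, which weakens a correlation. When each ph+E(z) library in turn was held out of the calls and used only for the second change, the median change of the genes that had risen was -0.248, -0.723 and -0.652. Random gene sets matched on level had a 2.5 percentile of -0.0712, -0.0946 and -0.0896. Such sets also leave out deviations that genes share, so their limits may be too narrow. For the genes that had fallen, the medians were 0, 0.189 and 0.168, and the upper limits of the central 95% of random sets 0.0764, 0.187 and 0.154. With ph+E(z) replicate 1 held out, the genes that had fallen were therefore not higher than random sets. The count of 62 was 128 without the library labelled control replicate 1, 32 and 28 without control replicates 2 and 3, 7 and 9 without ph+E(z) replicates 2 and 3, and 21, 24 and 39 without replicates 1, 2 and 3 of the group with all 3 targets. The count of 11 was 61 without the library labelled control replicate 1, 4 without control replicate 2 or 3, 30, 1 and 1 without ph+E(z) replicates 1, 2 and 3, and 4 and 5 without replicates 1 and 2 of the group with all 3 targets.

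**Figure D3:**
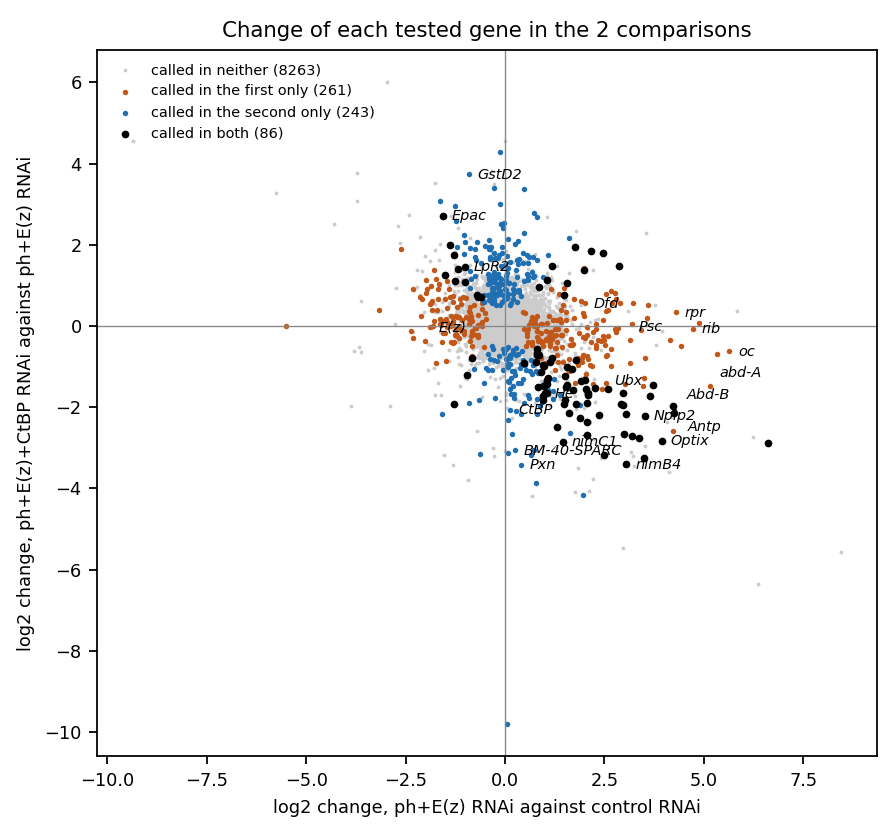
Log2 change of each of the 8853 tested genes with ph+E(z) RNAi against control (x axis) and on adding CtBP RNAi (y axis), with colours for genes called in neither, one or both comparisons. The lower right holds the 62 genes that rose and then fell, among them Antp at 4.26 and -2.14. Both axes contain the same ph+E(z) libraries.

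The comparison of ph+E(z)+CtBP RNAi with control RNAi asks what differs from control cells when all 3 are targeted. All 5 tested HOX genes were higher than in control cells, and all 3 treated libraries lay above all 3 control libraries for each. The log2 changes were 3.69 ± 0.36 for abd-A, 2.58 ± 0.29 for Dfd, 2.26 ± 0.31 for Abd-B, 2.11 ± 0.39 for Antp and 1.90 ± 0.39 for Ubx (adjusted p = 0.00105, 0.00181, 0.00422, 0.0144 and 0.0194). The HOX list was higher by camera (adjusted p = 6.2e-06, and adjusted p = 0.323 with an estimated correlation). Antp lost its call without replicate 1 (0.0696) or 2 (0.0684) of the group with all 3 targets. Ubx lost it without control replicate 2 (0.054) or 3 (0.0552) and without replicate 1 (0.0867) or 2 (0.0859) of the group with all 3 targets, so that 3 HOX genes were called without either of the latter libraries. Of the 228 genes that rose with ph+E(z) RNAi, 129 were also called higher here. Both comparisons use the same control libraries, so some of this overlap arises without any effect.

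In this comparison 861 genes changed, 494 higher and 367 lower, and 491 changed at least 2-fold, 313 higher and 178 lower. Groups did not overlap in 860 of the 861, and in 36.3% of all tested genes, where chance gives 10%. The transcription factor genes oc, rib, cad, ap and drm rose by 5.02 ± 0.30, 4.65 ± 0.32, 4.63 ± 0.31, 4.13 ± 0.33 and 3.81 ± 0.27. The peptidoglycan receptor genes PGRP-LA and PGRP-LC, neighbours on 3L, went from 1.29 ± 0.256 to 24.5 ± 5.69 and from 1.74 ± 0.428 to 30.4 ± 7.25 FPKM (adjusted p = 9.81e-05 and 0.000168). The cell death activators rpr and W (hid) went from 1.98 ± 1.05 to 59.0 ± 18.0 and from 2.52 ± 0.385 to 16.2 ± 5.68 FPKM (adjusted p = 0.000407 and 0.00153). Among genes that fell, the adjacent type IV collagen genes vkg and Cg25C went from 61.7 ± 6.80 to 4.42 ± 2.38 and from 80.9 ± 2.95 to 8.65 ± 3.04 FPKM, changes of -3.76 ± 0.37 and -3.20 ± 0.27 (adjusted p = 0.00106 and 0.000495). Pxn changed by -3.03 ± 0.39 and BM-40-SPARC by -2.82 ± 0.26 (adjusted p = 0.00332 and 0.000725). The chaperone gene Hsc70-3, whose protein works in the endoplasmic reticulum, fell by 0.84 ± 0.10 (adjusted p = 0.00225). The count of called genes was 1541 without the library labelled control replicate 1, 532 without control replicate 3, 560 without ph+E(z) replicate 2, and 298 and 319 without replicates 1 and 2 of the group with all 3 targets. Without these last libraries, 244 and 256 genes changed at least 2-fold.

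By list, 13 of 28 Polycomb target transcription factors were higher than in control cells, 15 adjusted over the list alone (camera adjusted p = 7.59e-13, and adjusted p = 0.323 with an estimated correlation). The count was 8 without replicate 1 of the group with all 3 targets. Markers of crystal cells and lamellocytes had 5 of 10 higher, 8 adjusted over the list alone (camera adjusted p = 2.54e-05, and adjusted p = 0.141 with an estimated correlation). The 5 were 3 without replicate 1 or 2 of the group with all 3 targets. peb went from 0.27 ± 0.062 to 7.36 ± 1.83 FPKM, a log2 change of 3.33 ± 0.28 (adjusted p = 0.000539). The crystal cell factor gene lz rose by 1.45 ± 0.23 (adjusted p = 0.00733). Plasmatocyte markers split, with 7 of 24 lower and 2 higher (camera adjusted p = 0.123). The higher members were Lac and the engulfment receptor gene drpr, named after their values were seen, and 12 were lower and 5 higher without the library labelled control replicate 1. Without that library the list was called lower (0.00218, median -0.66), as with array weights (0.00231) and the length correction (0.0411), with up to 0.371 under other alternatives. Those 2 higher calls were lost without control replicate 2 or 3, ph+E(z) replicate 2 or 3, or replicate 1 or 2 of the group with all 3 targets. Immune genes had 3 of 22 higher, 5 without the library labelled control replicate 1 and 1 without either other control library or replicate 1 or 2 of the group with all 3 targets. Adjusted over the list alone 8 were higher (camera adjusted p = 0.0289, and adjusted p = 0.323 with an estimated correlation). That list call was lost without the library labelled control replicate 1 (0.171), without replicate 3 of the group with all 3 targets (0.11) and with array weights (0.214). Cell cycle genes had 5 of 38 lower, 13 adjusted over the list alone (camera adjusted p = 6.2e-06, and adjusted p = 0.323 with an estimated correlation). The mitotic cyclin gene CycB went from 87.1 ± 11.1 to 46.2 ± 10.2 FPKM, a change of -0.92 ± 0.16 (adjusted p = 0.0112, and 0.0574 without replicate 1 of the group with all 3 targets). The count of 5 was 12 without the library labelled control replicate 1, 2 without control replicate 2 or 3, 3 without ph+E(z) replicate 1, 1 without ph+E(z) replicate 2 or 3, and 0 and 1 without replicates 1 and 2 of the group with all 3 targets. Ribosomal protein genes had 1 of 82 lower and a median of -0.40 (camera adjusted p = 1.78e-08, and adjusted p = 0.639 with an estimated correlation). They took 26.4% to 28.7% of FPKM with all 3 targets, 30.8% and 30.7% in control replicates 2 and 3, and 39.6% in the library labelled control replicate 1. By camera at its preset correlation, the list was called lower under all 22 alternatives, with an adjusted p of at most 0.000618. These include the fit without that library. Directional fry did not call the list (adjusted p = 0.108), nor did camera with an estimated correlation. The count of 1 was 6 without that library, 2 without ph+E(z) replicate 1 or replicate 3 of the group with all 3 targets and 0 without control replicate 3, ph+E(z) replicate 2 or replicate 1 of the group with all 3 targets. The other 17 lists were not called (camera adjusted p between 0.0527 and 0.903). Among them, the Notch list was called higher with a pseudocount of 1 (0.0475), without the trend (0.0337) and in a fit of the 2 groups (0.0374). It was also called without control replicate 2 (0.0249) or 3 (0.035), without ph+E(z) replicate 1 (0.0388), 2 (0.0492) or 3 (0.048) and without replicate 1 (0.029) or 2 (0.0322) of the group with all 3 targets, with up to 0.558 elsewhere. Neuron markers were called higher without control replicate 2 (0.0183) or 3 (0.0165) and without replicate 2 of the group with all 3 targets (0.044), with up to 0.643 elsewhere. The Hedgehog and Dpp list was called higher without a filter (0.0304), and the Wnt list lower with array weights (0.0249) and the length correction (0.0478), with up to 0.408 and 0.848 elsewhere.

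In the authors' deposited table, 774 genes had a q-value under 0.05 for ph+E(z) against control, and 263 of these were among the 347 called by limma. For the addition of CtBP RNAi, the authors' deposited table held 633 such genes, and 260 of them were among the 329. The authors' deposited table gave q = 0.00102 for Antp, Ubx, abd-A and Abd-B and 0.0325 for Dfd on adding CtBP RNAi. For ph+E(z) against control, the authors' deposited table gave q = 0.00102 for Dfd, 0.00271 for Ubx, 0.217 for Antp, 0.314 for Abd-B and 0.385 for abd-A. It also gave 0.00102 for ph-p in the authors' deposited table, where limma with all libraries gave an adjusted p of 0.486.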

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

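The transcript length correction and the covariance over protein-coding genes were chosen only after the data were seen. Over 169 results for named genes, 3117 values under the alternatives kept direction and side of the threshold, 578 lost the call, 8 gained it and 12 reversed. The cause was not tested for the changes given here. Leaving out each library in turn gave 108 to 602 changed genes for ph+E(z) against control RNAi, 89 to 1191 on adding CtBP RNAi and 298 to 1541 for all 3 targets against control. Changes of at least 2-fold numbered 102 to 288, 79 to 325 and 244 to 574, HOX genes called on adding CtBP RNAi 0 to 4, and HOX genes for all 3 targets against control 3 to 5. Genes higher and then lower numbered 7 to 128, and genes lower and then higher 1 to 61. Where a left-out library leaves 2 in its group, these are assumed to vary like the others. Array weights, which gave the library labelled control replicate 1 a weight of 0.0443, gave 2924, 2396 and 3278 changed genes, 552 and 475 changed at least 2-fold in the first 2 comparisons, 5 HOX genes on adding CtBP RNAi, and 425 and 377 genes changed in opposite directions. Fits of only the 2 groups compared gave 210, 793 and 378 changed genes, 307 changed at least 2-fold for all 3 targets, and 6 genes lower and then higher. Quantile normalization gave 17 of the last kind. An adjusted p under 0.01 in both comparisons left 10 genes higher and then lower. Each ph+E(z) library was also held out of the calls and compared alone with the 3 libraries with CtBP RNAi. Of the genes that had risen, 98 of 190, 62 of 87 and 71 of 100 were lower in all 3 against replicates 1, 2 and 3. For gene lists, camera with an estimated correlation called 0, 0 and 0, mixed fry called 14, 15 and 16, and directional fry called 7, 4 and 7. Directional fry called lists higher that camera had not called, RNA interference (0.00479) and apoptosis (0.0187) for ph+E(z) against control, and RNA interference (0.00817) and muscle (0.036) for all 3 targets against control. With the replicate block, 212 genes changed for ph+E(z) against control, 241 on adding CtBP RNAi and 593 for all 3 targets. The replicate block also left 1 HOX gene on adding CtBP RNAi, Abd-B (0.0286), with Antp at 0.0559 and Ubx at 0.107, and 40 and 7 genes changed in opposite directions, and with median-ratio rescaling these were 216, 1 and 7 for the first comparison, the HOX gene and the genes lower and then higher. The labels do not say that a number marks a shared culture, and the deviations of same-numbered libraries correlated across genes between -0.137 and 0.197. Same-numbered control and ph+E(z) libraries correlated at 0.197, 0.046 and 0.14, but control replicate 2 correlated best with ph+E(z) replicate 3 (0.102). Same-numbered libraries with all 3 targets correlated below 0 with both other groups, so not every library correlates best with its own number. The block also called CtBP partner factors higher for ph+E(z) against control (0.0284) and neuron markers higher for all 3 targets against control (0.0383). Reversed values all concern knockdown targets that had not passed the test. For ph-d with ph+E(z) RNAi against control, the change was -0.136 with array weights and -0.189 to 0.72 over left-out libraries, lowest without the library labelled control replicate 1. For ph-d with all 3 targets against control it was -0.372 with array weights, -0.102 with the length correction and -0.316 to 0.593 over left-out libraries, lowest without the same library. For CtBP in the first comparison it was -0.0508 with the length correction. On adding CtBP RNAi, ph-p was at -0.0343 with array weights and at -0.0438 to 0.199 over left-out libraries, lowest without replicate 3 of the group with all 3 targets. E(z) was there at 0.00579 with quantile normalization, 0.0941 with array weights and -0.116 to 0.142 over left-out libraries, above 0 without ph+E(z) replicate 1 (0.142) and without replicate 2 of the group with all 3 targets (0.0245). The length correction gave 391, 387 and 950 changed genes. The covariance over 7945 protein-coding genes was -0.0721, against -0.0251 in simulated libraries (range -0.0317 to -0.0209 over 100 draws). It lies outside that range, which may be too narrow because genes were drawn independently. The correlation over these genes was -0.257, within the simulated range of -0.352 to -0.254. Total depth is not given in the sources used here, but single reads show as equal steps in some short genes. The 5 libraries with snoRNA:Psi28S-3571 hold 12 to 13.5 FPKM, 1 step each, so calls of such genes rest on single reads.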

Other observations

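The tests of sequencing depth and of exchanged labels, of shared ph+E(z) libraries and of weaker knockdown of E(z) or ph were chosen only after the results were seen. Among genes not described so far, CG13936, chosen after its values were seen, went from 0.567 FPKM with control RNAi to 115 with ph+E(z) RNAi and 14 with all 3 targets, log2 changes of 6.61 and -2.89. Ugt36Ba (Ugt37C2) rose by 2.06 ± 0.23 on adding CtBP RNAi (limma adjusted p = 0.00426), from 3.66 ± 1.32 to 16.5 ± 2.59 FPKM. Ugt58Fa (Ugt317A1), another UDP-glycosyltransferase gene, went from 24.8 ± 8.91 to 2.2 ± 0.513 FPKM, a change of -3.17 ± 0.34 (adjusted p = 0.00405). The pseudouridylation guide snoRNA:Psi28S-3385a was listed at 0 in all control libraries and at 15.1 ± 6.87 FPKM with ph+E(z) RNAi, and snoRNA:Psi28S-3316a was at 23.3 ± 9.0 FPKM in control libraries and listed at 0 in the others. Their values lie at 1 or 2 times a single step, within 0.05 of a step, after scaling by the value of 1 read in each library, so they are 1 or 2 reads and no change in expression is read from them. How RNAs of this length were kept in the libraries is not given in the sources used here.

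The library labelled control replicate 1 stood apart from the other 2 control libraries, with a low ph-p value. Loss of long transcripts is argued against as the whole cause, since its deviation had an SD of 0.928 after each library's trend with transcript length was removed and 1.01 before. Lower depth is argued against, since 1 read was worth less FPKM in this library than in any other, with a smallest ratio of 1.06. An exchange of labels with a knockdown library is argued against by E(z) at 43.4 FPKM, while Antp, Ubx, abd-A and Abd-B were at 0.0684 FPKM or less. RNA quality, library preparation and the state of that culture remain open, and no biological explanation was tested.

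Most genes that rose with ph+E(z) RNAi had a change below 0 when CtBP RNAi was added. These were 168 of 228, with 62 called lower, while 60 had a change above 0. The weakest of the 3 medians against a held-out library was -0.248, where the 2.5 percentile of random gene sets was -0.0712. Random sets leave out deviations that genes share, so this limit may be too narrow. Holding out 1 library also keeps any deviation common to the ph+E(z) libraries. The shared ph+E(z) libraries are therefore argued against as the whole cause only if genes and libraries deviate independently. A dilution of the other knockdowns by the added dsRNA could lower the same genes. It cannot be told apart from an effect of CtBP, since the estimate for E(z) was -0.0162 with a 95% interval of -0.42 to 0.39, and that for ph-p was 0.117 with an interval of -0.94 to 1.18. The spread shared with the control libraries widens the latter, which was -0.23 to 0.46 without the library labelled control replicate 1, and neither interval for ph-p excludes a rise. The knockdown of CtBP that the design names remains a candidate explanation, and a CtBP knockdown alone was not analysed here.

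As a list, plasmatocyte markers were lower when CtBP RNAi was added, with 13 of 24 called lower, 11 not called and 3 with a change above 0. The list call was lost in camera with an estimated correlation (adjusted p = 0.163). A trend with transcript length is argued against, since 13 markers were still called lower after it was removed. A lower share of plasmatocyte-like cells would lower all markers by about the same amount only if the other cells lacked them, which was not measured. In that case alone, a lower share is argued against by 8 markers whose 95% intervals lay wholly above the list median of -1.78. Among them were LanB1, LanB2, srp, ush, crq and drpr. A loss of cells that differ in only some of these markers, and a response to the knockdown of CtBP, may each still account for the pattern.

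As a hypothesis, genes that respond to ph+E(z) RNAi may lie in shared chromosomal domains. Among 208 genes that rose and have a position, 31 pairs were adjacent tested genes that do not overlap, against 4.25 on average and at most 9 in the central 95% of 10000 random sets of the same size. The one-sided permutation p was 0.0001, the smallest these sets can give, and 0.000133 adjusted over 4 tests. The pairs include Ubx with abd-A, Dfd with Antp, nub with pdm2, nimB3 with nimB4, PGRP-LA with PGRP-LC, and W with rpr. Among these named pairs the gap ran from 294 bases for nimB3 and nimB4 to 211893 for W and rpr. It was 93824 bases for Dfd and Antp and 72787 for Ubx and abd-A, and genes that were not tested may lie between. The 113 genes that fell held 2 pairs (permutation p = 0.354). On adding CtBP RNAi, 160 genes that rose held 12 pairs and 152 that fell held 15, against 2.52 and 2.21 in random sets (permutation p = 0.0001 each, the smallest these sets can give). Transcription that runs through into the next gene, and the shared ancestry of neighbouring copies such as the nimB genes, remain open.

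The splits of 6 libraries into 3 and 3 are too few, at 10, for a share under 0.05. For ph+E(z) against control the real split gave 347 changed genes, 263 changed at least 2-fold, 7 lists and 5 HOX genes, and the highest of the other splits 3, 3, 10 and 0. On adding CtBP RNAi these were 329, 229, 9 and 3, and the highest others 1, 1, 9 and 0. For all 3 targets against control they were 861, 491, 6 and 5, and the highest others 2, 2, 9 and 0. In these 3 comparisons, 7, 2 and 8 of the 10 splits, the real one included, called at least as many lists as the real one. The number of lists called at the preset correlation therefore did not set the real groups apart from mixed ones. In 100 splits of the 9 libraries, only the real one, included among them, reached the 62 genes higher and then lower. The same held for the 11 genes lower and then higher, and the highest others were 2 and 1. Splits that mix the groups add the group differences to the spread and call few genes. The outcome was thus largely fixed in advance. These counts neither exclude chance nor show that the opposite directions exceed it.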
